A study of Mus musculus with 20 samples.

How the data were processed

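RNA-seq was deposited for 20 libraries of mouse lung tumours, all labelled as squamous carcinoma (HiSeq2500 and Illumina TruSeq RNA per the labels). The labels call the source primary lung tumour-derived cells, while the extraction protocol names EAF-fixed, paraffin-embedded tissue. The authors deposited 2 tables of raw read counts per Ensembl gene, one for the 6 libraries of run 1 and one for the 14 of run 2. The submitters' processing notes name TopHat, TopHat2 2.0.12, Bowtie 1.1.0, SAMtools 0.1.19, DESeq2 and the build NCBIM37. The counting tool, the annotation release and the strand setting are not given in the sources used here. Each table lists only genes with at least 1 count in its libraries (23468 and 35567 genes, 21961 in both), and no column was left unused. Columns of run 1 are headed 3462 with other index sequences, while the labels say 3463, and they were matched by code, tag and order, so that match is an assumption. Gene symbols of run 2 came from the run 1 table and from the reference annotation.

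Groups were taken from the labels: untagged, small and big in run 1 (2 libraries each), and 15GFE (4), 16GFE (7), KTS (2) and KP (1) in run 2. All libraries are labelled with one genotype, and the groups are only the series of the specimen codes. In run 2 the libraries of 15GFE and 3 of 16GFE were in lane 7 and the rest in lane 8. Totals were 10.6 to 14.7 M counts in run 1 and 1.83 to 9.69 M in run 2, so levels under 1 CPM rest on few reads. The smallest chi-square per degree of freedom between libraries of a run was 8.88, so no pair is a copy.

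Counts were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM factors, filterByExpr by group, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The 14 libraries of run 2 were fitted in 4 groups with 1 shared spread. KTS was compared with the mean of the 15GFE and 16GFE group means. For the runs, counts of small and big of a code were summed (4 against 4, genes in both tables). The same code paired the libraries: deviations of a code from its run correlated at 0.543, 0.485, 0.738 and 0.276 with the same code in the other run and at most 0.015 with another code, so fits with the replicate block are given beside the others. Centring over 4 codes by itself lowers the correlation with another code. Among all 14 run 2 libraries, 2 of the 6 run 1 libraries correlated most with their own code by Spearman. For small and big the correlation over 2 pairs was 0.161.

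Gene lists (35 fixed, 33 set-tested at most, 5 or more members past the filter) covered squamous, lung epithelial, immune, stromal, programme and RNA quality genes and were tested with limma 3.58.1 camera (preset correlation 0.01), with the correlation estimated, and with fry. Log2 CPM used a prior count of 2. A list score is the mean log2 CPM of its members. Relations used permutation tests (100000 resamples, exact for n under 10, 2-sided). Random lists (10000) were matched over 20 bins of expression. DESeq2 1.42.0, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 under Python 3.11.15 were also used. A gene with no count in a group was set against a floor of 3 counts over the group. SE of a log2 fold change of a gene is from the fit. The SE beside a list median is the SD of its members' log2 fold changes over the square root of their number. It takes genes as replicates and does not measure the spread between libraries.

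Named genes were chosen by a rule fixed before the data were examined: among genes past adjusted p 0.05 with mean log2 CPM of at least 1 and a non-predicted symbol, the 12 largest rises and 12 largest falls whose groups did not overlap, filled up with others, plus up to 4 called members of each list with the highest CPM, or 2 where none was called. Engineered and sex-linked genes were always given, and for KP the 12 genes farthest above and below the other 13 libraries. For the spread, 24 genes of largest SD with mean log2 CPM of at least 3 were considered. List members whose call in KTS was lost in at least 1 setting (Bpifa1, Scgb3a1, Muc5b, Foxj1, Csf1r, Cd4, Cd8a, Krt19, Mki67, Top2a, Vim, Dnajb1 and Fn1) were left out of the text after their values were seen, as were those members of the run comparison (mt-Nd4, Sprr1a, Stat1, Cd68, Pgk1 and Pcna). Not every other gene the rule gave is printed, and which were printed was chosen after their values were seen. Arid5a, Stk40, Myh8 and Igkv19-93 lie outside the rule and were named because a setting called few genes.

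The method was tested on simulated data with 200 changed genes, 50 at each of 1.5-, 2-, 4- and 8-fold. At 4-fold it recovered 80% of the 50 for 16GFE against 15GFE, 68% for KTS, 88% for the runs and 84% for big and small, at 2-fold 46%, 26%, 64% and 26% and at 1.5-fold 6%, 2%, 16% and 0%, with 0 in the wrong direction, and called 2, 4, 6 and 1 unchanged genes. Alternatives covered the test, the normalization, the filter, each library left out, lane, replicate block and depth. Background alternatives were added after the data were examined: the share of counts in olfactory receptor genes as covariate, and leaving out the 5 libraries where it was highest. Also added then were thinning of all run 2 libraries to the smallest total and relations centred within each code series and permuted within it (all orders), or taken within 16GFE. Silent genes (4177) were those with at most 2 counts over the 4 run 2 libraries with the fewest olfactory receptor counts. A run 2 score on one scale with run 1 used genes in both tables and factors over all 20 libraries. For the same-code check, log2 CPM was centred per gene within each run and compared by Spearman correlation.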

Results

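The series holds 20 RNA-seq libraries of mouse lung tumours, all labelled as squamous cell carcinoma with conditional Sox2 overexpression and biallelic loss of Pten and Cdkn2ab after intratracheal Ad-K14-Cre. Run 1 gave 6 libraries and run 2 gave 14, which carry 14 specimen codes, 4 of them in both runs. The labels do not explain the code series (15GFE, 16GFE, KTS, KP) or the tags small and big. They also do not say that replicates come from separate animals, so a p-value may measure technical spread.

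Sox2, Cdkn2a and Cdkn2b separated the libraries labelled KTS and KP from the GFE libraries of run 2. Sox2, the transcription factor overexpressed by design, had a mean of 71.3 CPM (range 38.5 to 119) in the 11 GFE libraries of run 2 and 124.8 CPM (51.1 to 197.8) in the 6 libraries of run 1. It had 0.464 and 1.33 CPM in the 2 libraries labelled KTS and 5.03 CPM in the library labelled KP. Cdkn2b, a cell cycle inhibitor deleted by design, was at 0 to 0.593 CPM in the 11 GFE libraries, at 13.8 and 18.1 CPM in the libraries labelled KTS and at 19.99 CPM in the library labelled KP. Cdkn2a, which encodes further inhibitors at the same locus, ranged from 0.224 to 4.29 CPM in the GFE libraries, against 16.2 and 23.5 CPM for KTS and 26.6 CPM for KP. Pten, the phosphatase that restrains PI3K signalling, was at 198 to 392 CPM in the GFE libraries, 355 and 365 CPM for KTS and 280.1 CPM for KP. A gene count includes undeleted exons and reads from host cells and may miss a transgene, and Sox2 lies within Sox2ot, so the level of Pten does not test its deletion. CPM values of the runs were normalised within each table.

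**Figure D1:**
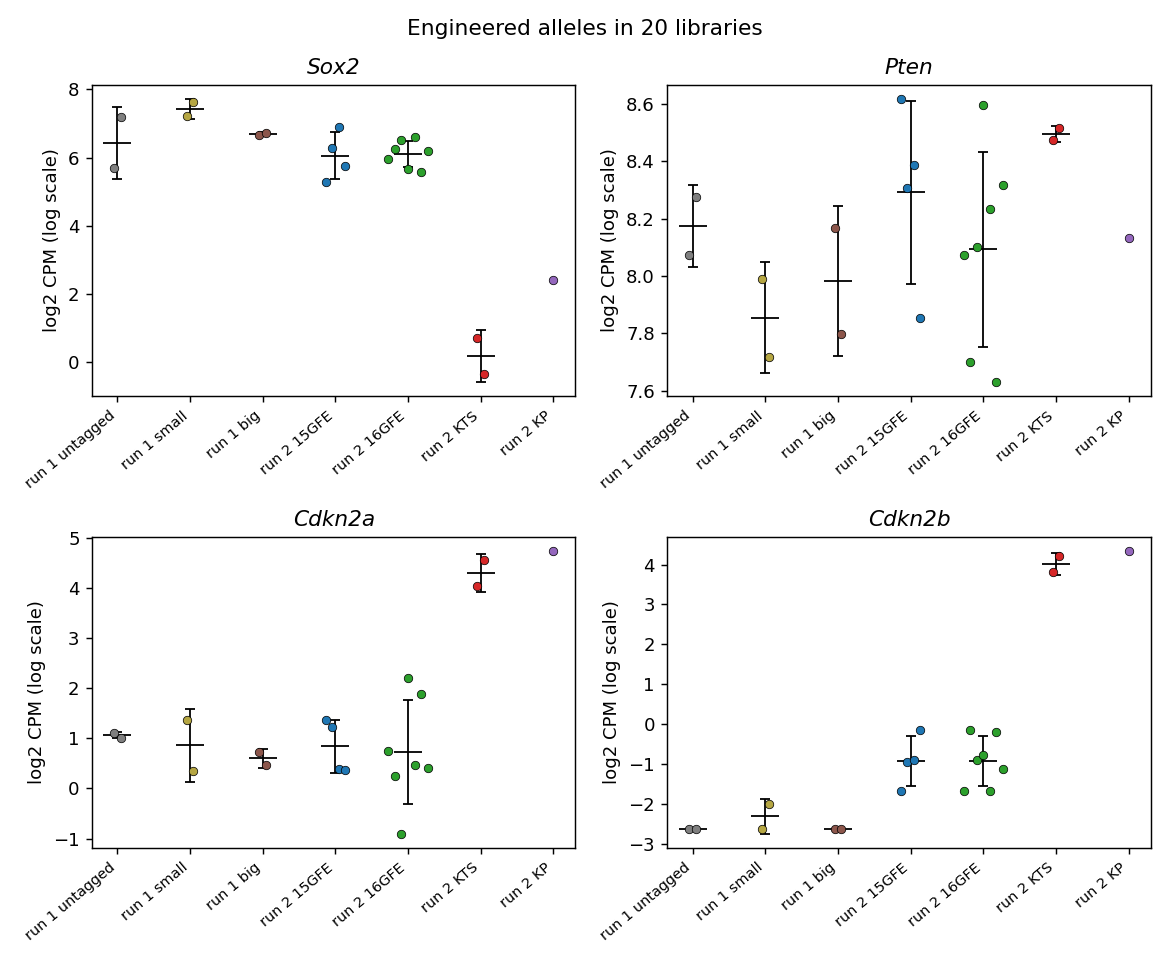
Log2 CPM (y axes) of Sox2, Pten, Cdkn2a and Cdkn2b in each of the 20 libraries (points), by group on the x axis; horizontal marks are group means and bars 1 SD where a group has more than 1 library. The libraries labelled KTS and KP lie below the others in Sox2 (at most 5.03 CPM) and above the others in Cdkn2b (at least 13.8 CPM).

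The sex-linked transcripts differed between the GFE libraries. Xist, the RNA that coats the inactive X chromosome, ranged from 1.07 to 3251 CPM in the 11 GFE libraries. The Y-linked Ddx3y ranged from 0 to 131 CPM, Uty from 0.118 to 94.97 CPM, Eif2s3y from 0 to 75.1 CPM and Kdm5d from 0.223 to 59.7 CPM. Xist was at least 2551 CPM, with Ddx3y at most 0.448 CPM, in 15GFE024, 16GFE001, 16GFE017, 16GFE018 and 16GFE011. In the other GFE libraries Xist was at most 12.9 CPM and Ddx3y at least 42.2 CPM. The code series were therefore not balanced in these transcripts. Xist had 1.06 and 6034 CPM in the libraries labelled KTS and 4237 CPM in the library labelled KP.

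Compared with the 11 GFE libraries, the 2 libraries labelled KTS had far lower squamous transcripts and far higher alveolar type 2 transcripts. Krt5, a keratin of basal cells, averaged 463 CPM in GFE and 1.73 CPM in KTS (log2 fold change -8.08, SE 0.58), and the desmosomal genes Pkp1 (-7.26, SE 0.45) and Dsg3 (-9.57, SE 0.64) fell with it. Sftpb, a surfactant protein, averaged 361 CPM in GFE and 6544 CPM in KTS (4.18, SE 0.32), and Slc34a2, the phosphate carrier of alveolar type 2 cells, rose from 655 to 6177 CPM (3.24, SE 0.30). Gkn2, a gastric mucosal protein, rose from 0.0900 to 78.7 CPM (9.88, SE 0.39).

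Of the 24 measured genes of basal and squamous epithelium, 22 fell in KTS, and 22 did so when adjusted over the list alone. The median log2 fold change was -5.47, or -4.83 with the 1 member that had no count in KTS at its bound. Krt6a (-8.76) and Perp, a desmosomal p53 target (-3.76), were among them. Krt6a and Krt6b (-9.80) are paralogs, so their split of reads is uncertain. The list was lower by camera (adjusted p = 1.38e-21), with adjusted p = 0.0941 with an estimated correlation. Of 25 genes of cornified and suprabasal epithelium, 18 fell and 20 when adjusted over the list alone, with a median of -4.33, or -3.50 with 5 members at their bound. They included Krt13 (-9.37), Krt4 (-8.46) and Calml3 (-7.91), with camera adjusted p = 7.31e-13 and adjusted p = 0.0941 with an estimated correlation. Psca (-9.25), a surface antigen of epithelia, and Clca4 (-9.65), of a family of chloride channel regulators, fell as well.

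Pglyrp4, a bactericidal pattern receptor, Csta, a cornified envelope protease inhibitor, and Alox12b, a lipoxygenase of the skin barrier, had no count in either library labelled KTS. Against a floor of 3 counts over both libraries they were at least 221-fold, 187-fold and 83.8-fold lower. Sprr3, a cornified envelope precursor, had 2 counts in all, a ratio of 968.5 (95% counting interval 268 to 7997), and Cnfn had 1, a ratio of 913 (164 to 36080.0).

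All 15 measured alveolar type 2 genes rose (15 adjusted over the list alone), with a median of 2.53. Sftpc rose by 2.55 and Sftpa1 by 3.05. The list was higher by camera (adjusted p = 4.96e-15), with adjusted p = 0.197 with an estimated correlation. Among alveolar type 1 genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0537). Ager, a receptor of type 1 cells, rose by 2.35 and Gprc5a by 2.11, while Hopx fell by 2.17 on the log2 scale. Of 12 club cell genes 9 fell (10 adjusted over the list alone, median -2.79), among them the cytochrome Cyp2f2 (-3.41) and the carbonyl reductase Cbr2 (-2.27), with camera adjusted p = 0.000166 and adjusted p = 0.256 with an estimated correlation. Mucous and gastrointestinal-type genes went both ways, with 8 higher and 4 lower (8 and 4 adjusted over the list alone), and camera adjusted p = 0.00953, or adjusted p = 0.448 with an estimated correlation. Hnf4a, a transcription factor of gut and liver, rose by 6.07 and Cldn18, a tight junction protein, by 2.33.

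The genes with the largest rises also held Meg3 (6.69), Rian (6.72), Mirg (5.17) and Dlk1 (6.65), transcripts of 1 imprinted cluster, whose overlapping annotations leave the share of each uncertain. Apob, the apolipoprotein of lipid particles, rose by 6.73, Ros1, a receptor tyrosine kinase, by 6.49, Pkhd1, a protein of primary cilia, by 5.34, Itih2 by 4.82, the elastase Cela1 by 4.64 and the proton pump subunit Atp6v0a4 by 4.60. U2, a spliceosomal RNA with many genomic copies, rose by 7.84, and its reads may fall on any copy.

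Immune transcripts were lower in KTS. Of 16 type I interferon response genes 15 fell (16 adjusted over the list alone, median -3.25), among them Irf7 (-4.46), a regulator of the response, Oas2 (-4.32) and Oasl2 (-3.17), with camera adjusted p = 1.98e-14 and adjusted p = 0.0941 with an estimated correlation. Of 18 genes of antigen presentation and the interferon gamma response 13 fell and 1 rose (13 and 1 adjusted over the list alone), and the invariant class I chain B2m (-2.18), the peptide transporter Tap1 (-2.24), Nlrc5 (-2.66) and Gbp2 (-4.47) fell. Camera gave adjusted p = 1.53e-06, and adjusted p = 0.392 with an estimated correlation. T cell genes fell in 16 of 18 cases (18 adjusted over the list alone), including the receptors Il7r (-2.06) and Il2ra (-2.12), with camera adjusted p = 5.80e-08 and adjusted p = 0.256 with an estimated correlation.

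Of 19 neutrophil genes 10 fell and 1 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 0.000794 and adjusted p = 0.388 with an estimated correlation. Ltf, lactoferrin of neutrophil granules and glandular secretions, averaged 7439 CPM in GFE and 23.96 CPM in KTS (-8.28), S100a8 fell by 3.06 and Csf3r, the receptor for granulocyte colony stimulating factor, by 2.03 on the log2 scale. Hdc, which makes histamine, rose by 1.22. Of 18 chemoattractants and inflammatory cytokines 11 fell and 1 rose (13 and 1 adjusted over the list alone), with Ppbp (-7.19), Il1a (-4.38) and Il1b (-2.36) among those lower, camera adjusted p = 0.000178 and adjusted p = 0.201 with an estimated correlation. Of 17 macrophage and monocyte genes 12 fell and 1 rose (12 and 2 adjusted over the list alone), with the lysosomal Cd68 (-1.70) and the complement gene C1qa (-1.76) lower, camera adjusted p = 0.00382 and adjusted p = 0.395 with an estimated correlation.

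Other groups moved less. Of 20 Nrf2 target genes 6 rose, among them Gclc (2.38) and Me1 (1.59), enzymes of glutathione and NADPH supply, and 5 fell, among them Gsta4 (-2.15) and Abcc1 (-1.20). The simple epithelial keratins Krt8 (1.35) and Krt18 (2.23) were among the 5 of 16 epithelial adhesion genes that rose, and 2 fell. Of 16 hypoxia and glycolysis genes 2 rose and 6 fell, including the oxygen sensor Egln3 (-2.92). Of 15 mesenchymal transition genes 4 fell, including the matrix protein Tgfbi (-1.44). In these 4 lists camera gave adjusted p = 0.433, 0.433, 0.207 and 0.0923, and fry called the mesenchymal list (adjusted p = 0.00186). Counts adjusted over the list alone were 6 and 6 for Nrf2, 5 and 3 for adhesion, 2 and 6 for hypoxia, and 0 and 4 for the mesenchymal list, higher and lower in turn.

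Of the other lists, B and plasma cells had 8 of 14 genes lower, natural killer cells 3 of 9, neuroendocrine cells 4 of 11, ciliated cells 2 of 15, cardiac and skeletal muscle 3 of 15, replication-dependent histones 6 of 14 and immediate early and stress genes 5 of 16. Endothelial cells had 2 of 14 genes higher, mitochondrial transcripts 2 of 10 and ribosomal proteins 3 of 27. Proliferation had 6 lower and 1 higher. Camera called these 11 lists, with adjusted p between 0.00162 and 0.0442, and with adjusted p between 0.337 and 0.597 with an estimated correlation. Olfactory receptor genes, silent in lung, took 0.00224% and 0.00196% of counts in KTS, 0.00143% in 15GFE019 and 0.01004% to 0.146% in the other 10 GFE libraries. The neuroendocrine score was -0.66 and -0.76 in KTS and -0.85 in 15GFE019, and the ciliated score 1.58 and 1.07 in KTS and 1.04 in 15GFE019, while 16GFE019, with the highest share, had the highest GFE scores (2.07 and 2.85). Without the 5 libraries of highest olfactory receptor share, a setting added after the data were seen, 4 lists missed the threshold. These were the neuroendocrine (camera adjusted p = 0.0626), endothelial (0.0682), mitochondrial (0.0938) and ribosomal (0.556) lists. The ciliated and natural killer lists passed it (camera adjusted p = 0.0256 and 0.00530). Genes of p53 targets (7 lower and 1 higher of 18), Wnt and Notch targets (3 lower and 2 higher of 14), fibroblasts and matrix (2 lower and 1 higher of 16), smooth muscle (1 lower of 10), erythroid cells (1 lower of 8) and adipocytes (0 of 10) gave no camera call, with adjusted p between 0.0537 and 0.957, while fry called p53 targets (adjusted p = 0.00186) and smooth muscle (adjusted p = 0.00465). Fibroblasts had a median of -0.32 while camera placed them above the other genes, since the median over all genes tested was -0.36, or -0.50 with upper-quartile factors.

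The edgeR test of KTS against GFE (n = 2 and 11) called 6253 of 23860 genes, 3252 higher and 3001 lower. Krt5, Hopx, Cyp2f2, Irf7, Tap1, Nlrc5, Gbp2, Il1a, Il1b, Me1, Krt8, Pkhd1 and Atp6v0a4 overlap other annotated genes, so their levels are uncertain. The groups did not overlap in 6057 genes (25.39%, against 2.56% by chance). Without the library labelled KTS046 the count was 3172 and without the library labelled KTS093 it was 3610. All KTS libraries were sequenced in lane 8, and 4450 genes were called within that lane and 4237 with lane as a covariate.

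**Figure D2:**
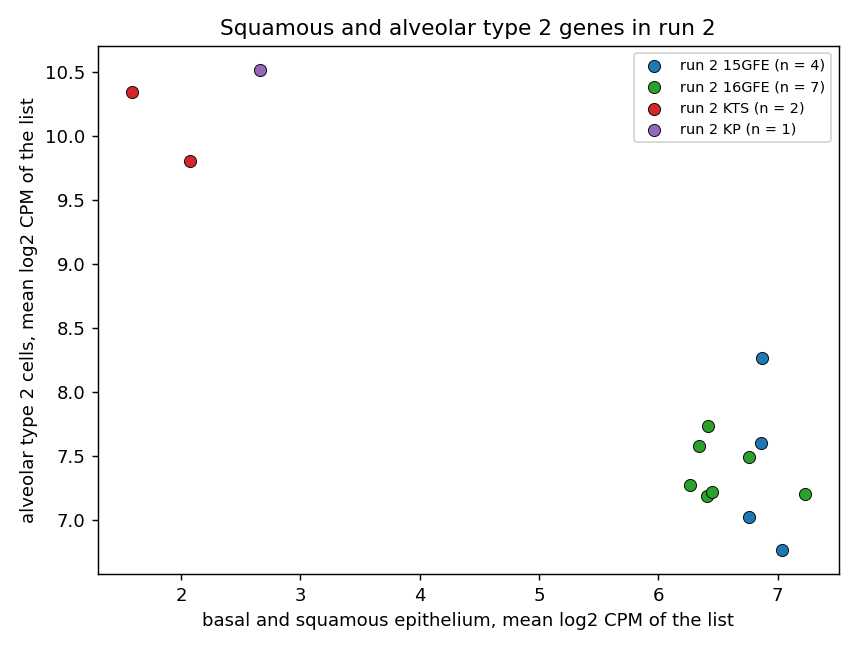
Mean log2 CPM of the basal and squamous list (x axis) and of the alveolar type 2 list (y axis) in the 14 libraries of run 2, 1 point per library, coloured by group. The 11 GFE libraries lie between 6.27 and 7.23 on the x axis, and the libraries labelled KTS and KP lie at 2.08, 1.59 and 2.66 with alveolar type 2 values of 9.80, 10.34 and 10.51.

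The library labelled KP, a single library given as values only, had an alveolar type 2 score of 10.51 (mean log2 CPM; 11 GFE libraries 6.76 to 8.26) and a squamous score of 2.66 (6.27 to 7.23). Its type I interferon score was 3.60 (mean 5.51). Chi3l3, a chitinase-like protein of alternatively activated macrophages, reached 5366 CPM against at most 958 CPM in the other 13 libraries of run 2. The neutrophil antigen Cd177 reached 206.5 CPM (at most 49.9), the mannose receptor Mrc1 286 CPM (at most 105.7) and the mucus cell gene Clca3 67.1 CPM (at most 9.56). Below all others lay the haemoglobin gene Hba-a1 at 9.34 CPM (at least 36.9), the chemokine Cxcl2 at 1.20 CPM (at least 3.41), the glycosyltransferase B4galnt3 at 1.08 CPM (at least 4.64) and Cd24a, a surface glycoprotein, at 85.6 CPM (at least 194.6). Its cornified score was 2.78 (3.21 to 4.47), and Krt13 and Krt4 had log2 CPM of 8.10 and 8.22.

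Within run 2, the 7 libraries with 16GFE codes had lower immediate early transcripts than the 4 with 15GFE codes. Egr1, a transcription factor induced within minutes of a stimulus, averaged 41.0 CPM in 16GFE and 265 CPM in 15GFE (log2 fold change -2.68, SE 0.44), Fos 20.4 and 110.7 CPM (-2.41, SE 0.36), Junb 80.3 and 193.9 CPM (-1.27, SE 0.19) and the phosphatase Dusp1 84.4 and 231 CPM (-1.45, SE 0.26). The groups overlapped for Egr1 (SD of log2 CPM 0.52 in 16GFE and 1.62 in 15GFE). Of the 16 immediate early and stress genes 5 fell, and 16 did so when adjusted over the list alone, with a median of -1.25. The list was lower by camera (adjusted p = 1.24e-16) and by fry (adjusted p = 0.0413), with adjusted p = 0.148 with an estimated correlation. Dusp1 and Junb overlap other annotated genes, which leaves their level uncertain.

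Genes of inflammation lay lower as well. Cxcl1, a neutrophil attracting chemokine (-1.65), and Ptgs2, the inducible cyclooxygenase (-1.41), were the 2 called of 18 chemoattractants and inflammatory cytokines (6 adjusted over the list alone), with camera adjusted p = 2.44e-06, fry adjusted p = 0.0413 and adjusted p = 0.148 with an estimated correlation. Socs3, a feedback inhibitor of cytokine signalling, fell by 1.39, the urokinase receptor Plaur by 1.28, Rgs1, a regulator of G protein signalling in leukocytes, by 1.59, the endothelial Apold1 by 1.61, the receptor Gpr171 by 1.51 and the potassium channel subunit Kcne4 by 1.47 on the log2 scale. The immunoglobulin gene Ighg2c fell by 2.29. The genes that rose were Lgr6, a stem cell receptor (1.06), Cckar, a cholecystokinin receptor (1.24), and Mybpc1, a muscle protein that overlaps another gene (3.30). Sox2 (-0.03), Pten (-0.19), Cdkn2a (0.09) and Cdkn2b (-0.18) did not pass the test.

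Squamous genes did not separate the code series, with 0 of 24 called (3 adjusted over the list alone, median -0.28), camera adjusted p = 4.50e-06 and adjusted p = 0.383 with an estimated correlation. Cornified (0 of 25 called) and alveolar type 2 genes (0 of 15) gave camera adjusted p = 0.189 and 0.284. Neutrophils (11 of 19 lower adjusted over the list alone, median -0.66) and mesenchymal genes (7 of 15, median -0.44) gave camera adjusted p = 3.76e-08 and 0.000293, with adjusted p = 0.164 and 0.148 with an estimated correlation. B and plasma cells (7 of 14, median -0.78) and hypoxia and glycolysis (4 of 16, median -0.41) gave camera adjusted p = 2.55e-06 and 6.39e-08. With an estimated correlation these were 0.313 and 0.28. Cardiac and skeletal muscle (7 of 15 higher adjusted over the list alone, median 1.86) and adipocyte genes (5 of 10, median 1.66) had 0 members called, with camera adjusted p = 0.00210 and 0.00898, and adjusted p = 0.519 and 0.507 with an estimated correlation. With lane as a covariate the mean log2 fold change of the muscle list went from 1.996 to 0.489 (camera adjusted p = 0.684) and that of the adipocyte list from 1.483 to 0.538 (adjusted p = 0.746). In all camera called 21 of 33 lists, 0 with an estimated correlation and 3 by fry. Other drawn splits of the same 11 libraries gave a median of 15 lists by camera, so its preset correlation calls many lists for arbitrary groups. T cells had a median of 0.19 while camera placed them below the other genes (adjusted p = 0.107). The median over all genes was 0.18. The share of counts in olfactory receptor genes averaged 0.0511% in 16GFE and 0.0191% in 15GFE, and depth 4.98 and 7.85 M counts.

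The edgeR test (n = 7 and 4) called 34 of 23860 genes, 3 higher and 31 lower. The groups did not overlap in 473 genes (1.98%, against 0.606% by chance). DESeq2 called 273, upper-quartile factors gave 20, no genes were called by edgeR with lane as a covariate (3201 at an unadjusted p under 0.05) or within lane 7 (3143), and 11 were called among the 11 libraries alone. With all libraries thinned to the smallest total, added after the data were seen, 21 were called. Leaving out 15GFE019, 15GFE021 or 16GFE020 left 0 genes (1607, 2045 and 3009 at an unadjusted p under 0.05), and counts without 15GFE024, 16GFE011, 16GFE001 and 16GFE017 were 110, 52, 20 and 11. With the olfactory receptor share as a covariate, added after the data were seen, 3 genes were called, Kcne4 (-1.78), Arid5a (-0.93) and Stk40 (-0.88), and without the 5 libraries of highest share only Myh8 (4.61).

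**Figure D3:**
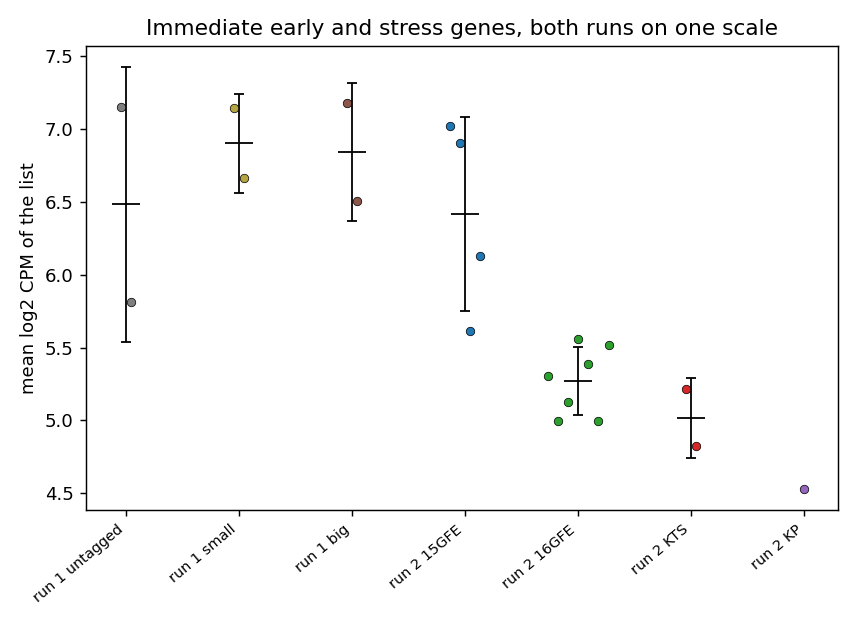
Mean log2 CPM of the 16 immediate early and stress genes (y axis) in each of the 20 libraries (points) by group on the x axis, normalised over both runs together; horizontal marks are group means and bars 1 SD. The 16GFE libraries reach at most 5.56, the 4 run 2 15GFE libraries lie at 5.61, 6.13, 6.90 and 7.02, and the 6 run 1 libraries, all with 15GFE codes, lie at 5.82 or above.

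Among the 14 libraries of run 2 the squamous list varied most (SD 1.97 of mean log2 CPM), then cardiac and skeletal muscle (1.52), cornified epithelium (1.43), alveolar type 2 cells (1.26) and the type I interferon response (1.13). In all 26 of 33 lists lay above the 95th percentile of random lists matched on size and expression, and 22 did among the 11 GFE libraries, where muscle (1.48, from 1.13 to 5.48) and adipocyte genes (0.94) varied most, both highest in 16GFE018. Single genes with the largest SD included Xist (5.17), Krt6a (4.10), Clca4 (3.94), Psca (3.85) and Krt17 (3.73).

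Neutrophil markers and their chemoattractants were related when the 11 GFE libraries were pooled (Pearson r = 0.826, p = 0.00224, adjusted p = 0.00896, Spearman rho = 0.864, p = 0.00105, 2-sided permutation tests, 4 relations). Without the 2 libraries farthest from the median r was 0.884, and within lane 7 it was 0.815 (n = 7, exact permutation p = 0.0222, adjusted p = 0.0889). Centred within each code series and permuted within it, added after the data were seen, r was 0.644 (exact permutation p = 0.0435, adjusted p = 0.165), and within 16GFE it was 0.807 (n = 7, exact permutation p = 0.0276, adjusted p = 0.110), so the relation did not pass within the series after adjustment. Squamous and neutrophil scores gave r = 0.632 (permutation p = 0.0389, adjusted p = 0.0778, rho = 0.518, p = 0.109), with r = 0.732 without the 2 farthest, 0.618 within lane 7 and 0.440 centred within the series. Sox2 and squamous scores (r = 0.357, permutation p = 0.279, adjusted p = 0.372, rho = 0.282, p = 0.401) and alveolar type 2 and squamous scores (r = -0.12, p = 0.718, adjusted p = 0.718, rho = -0.13, p = 0.714) showed no relation past the threshold. Without the 2 farthest these were 0.450 and -0.19, within lane 7 0.0440 and -0.01, and centred within the series 0.454 and -0.17. Lane 8 holds too few GFE libraries, and the libraries labelled KTS and KP form separate clusters and were left out.

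Where the same 4 codes were sequenced in both runs, mitochondrial genes differed most between the runs. In run 2 mt-Co3 (log2 fold change -14.86, SE 0.38), mt-Co2 (-13.20, SE 0.42), mt-Nd3 (-8.27, SE 0.27) and mt-Atp6 (-7.96, SE 0.49), subunits of the respiratory chain and ATP synthase, were lower. In contrast, mt-Atp8 was higher (9.12, SE 0.31). In the GFE libraries of run 2 mt-Co3 averaged only 0.283 CPM, and it had 1 count over both libraries labelled KTS. Its fold change therefore rests on few reads in run 2. The counting tool, the annotation release and the strand setting are not given for either table. The differences in these mitochondrial genes between the tables therefore cannot be read as expression, which was not tested. Of 12 mitochondrial transcripts 5 fell and 1 rose (9 and 1 adjusted over the list alone), with camera adjusted p = 5.53e-08, fry adjusted p = 0.00116 and adjusted p = 0.974 with an estimated correlation, and in the paired fit 9 fell and 1 rose. Outside the mitochondrion the ribonuclease Rnasek (-8.05), the channel gene Trpc2 (-5.97), Cpne1 (-5.79), Arhgap30 (-5.24) and Pou2f1 (-4.24) fell, and the transcript AY036118 (5.92), Lemd1 (4.83), the isoprenoid enzyme Idi1 (3.75), Irx2 (3.73), Pgap1 (3.12) and the splicing factor Srsf2 (2.55) rose. Of these, mt-Co3, mt-Atp6, mt-Atp8, Rnasek, Trpc2, Cpne1, Pou2f1, Lemd1, Idi1 and Srsf2 overlap other annotated genes, so their levels are uncertain. The 2 called of 19 cornified genes fell, and Cnfn was one of them (-1.25), while in the paired fit 4 fell and 1 rose (camera adjusted p = 0.107).

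Of 24 squamous genes 0 were called between the runs (median -0.27, camera adjusted p = 0.0709), and in the paired fit 2 fell (median -0.24, camera adjusted p = 0.0240, with adjusted p = 0.9504 with an estimated correlation and fry adjusted p = 0.5676). Of 15 alveolar type 2 genes 0 were called (camera adjusted p = 0.682), and in the paired fit 1 fell (camera adjusted p = 0.343). Replication-dependent histones had 1 of 14 genes lower (5 adjusted over the list alone), with camera adjusted p = 0.00176, fry adjusted p = 0.00297 and adjusted p = 0.259 with an estimated correlation, and in the paired fit 4 fell. Fry called the type I interferon response (7 of 16 lower, adjusted p = 0.0307) and proliferation (3 of 24 lower, adjusted p = 0.0403) in the paired fit only, with adjusted p = 0.616 for both with an estimated correlation. Genes called with more than a 4-fold difference overlapped another annotated gene in 46.2% of cases (95% interval 37.5 to 55.2), against 35.6% of all genes tested. All called genes did so in 43.5% of cases (39.6 to 47.6), so the excess was not particular to large differences.

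The edgeR test (n = 4 and 4) called 599 of 14887 genes, 324 higher and 275 lower in run 2, in the paired fit with the replicate block 2198 genes (947 higher, 1251 lower), and by DESeq2 2159. The groups did not overlap in 1911 genes (12.84%, against 2.86% by chance for exchangeable libraries, while these are paired by code). Without the codes 15GFE021, 15GFE024 and 15GFE028 the counts were 204, 309 and 257, and with the 6 run 1 libraries kept separate 1127. Of the 6 run 1 libraries 2 correlated most with the run 2 library of their own code by Spearman, 5 by Pearson and 6 when run 2 was centred over the 4 shared codes, a setting added after the data were seen, across genes, which are not independent replicates.

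Between the libraries of run 1 tagged big and small, of the same 2 codes, no gene passed the edgeR test. The keratins Krt6a and Krt5 had log2 fold changes, big against small, of -0.09 and -0.35, and Sox2 had -0.74 (SE 0.19). The muscle genes Myh6 and Ryr2 had 1.53 and 1.23, and Igj, the antibody joining chain, 1.18. Camera called 12 of 32 lists, such as cardiac and skeletal muscle (median 1.17, adjusted p = 0.000126), ciliated cells (-0.72, adjusted p = 0.00440), proliferation (-0.39, adjusted p = 1.39e-08), hypoxia and glycolysis (-0.39, adjusted p = 7.16e-07) and T cells (0.44, adjusted p = 4.74e-05), but 0 of them held with an estimated correlation (adjusted p = 0.854 for these 5) or by fry.

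The edgeR test (n = 2 and 2) called 0 of 15242 genes, with 223 at an unadjusted p under 0.05, and the paired fit with the replicate block called 0 with 460 at an unadjusted p under 0.05. DESeq2 called 1, the immunoglobulin gene Igkv19-93 (2.65). The groups did not overlap in 3534 genes (23.19%, against 33.3% by chance for exchangeable libraries). These libraries are paired by code, so the 23.19% cannot be read as less than chance. In simulated data of this size the test recovered 84% of genes changed 4-fold and 26% of genes changed 2-fold.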

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

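The rules of both checks were set before any value was examined, but the values checked were not all fixed then. They included the olfactory receptor share, whose use as a background measure came after the data were examined, and the share of satellite-like genes. The second check covered only lists that camera had called in the same data. In a group of 4 to 10 libraries a value was set apart when its gap to the nearest library exceeded Dixon's 95% critical share of the range. 5 of 80 values passed it, and chance flags about 1 in 20 groups, so these 5 are about as many as chance gives. In 16GFE018 the T cell score was 4.50 (next 3.26, gap share 0.693) and the Wnt and Notch score 4.34 (next 4.11, gap share 0.643). In 16GFE011 the epithelial adhesion score was 6.99 (next 6.59, 0.612). In 15GFE024 the type I interferon score lay above the next (5.53, gap share 0.903), and in 16GFE019 the share of satellite-like genes was 19.01% (next 8.98%, 0.573).

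For big against small, 7 of the 12 lists that camera called had opposite signs in the 2 codes, whatever the size, which was not tested. Big minus small, for 15GFE021 and 15GFE028 in turn, was 0.90 and -2.33 for ciliated cells (difference 3.23), 0.99 and -0.14 for T cells (1.14), and 1.15 and -0.41 for B and plasma cells (1.55). For proliferation it was -0.66 and 0.01 (difference -0.67), for epithelial adhesion -0.26 and 0.01 (-0.27), for hypoxia and glycolysis -0.92 and 0.04 (-0.95) and for ribosomal proteins -0.21 and 0.01 (-0.22). In these last lists 15GFE028 hardly changed, so only the sign was opposite.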

How the results depend on the processing

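Alternatives with the olfactory receptor share, thinning for 16GFE against 15GFE, the code series and the centring over the shared codes were chosen after seeing the data. The cause of each change was not tested unless stated. For 16GFE against 15GFE (34 genes) DESeq2 called 273, upper-quartile factors 20, no filter 98, the 11 libraries alone 11, lane as covariate 0, within lane 7 0 (fewer libraries), thinning to the smallest total 21 (fewer counts), background share as covariate 3 and without the 5 highest-background libraries 1, and leaving out 1 library gave 0 to 110. Its lists (21) fell to 0 with an estimated correlation, 3 by fry, 11 within lane 7 and 12 with thinning, with 17 to 22 on leaving out 1. Reversed lists were alveolar type 1 cells (0.147 with the background covariate, leaving out 1 from -0.42 to 0.099, highest without 15GFE019), endothelial cells (0.093, and -0.408 to 0.118), Nrf2 targets (0.052, and 0.049 without high-background libraries), ribosomal proteins (0.027), muscle (0.489 with lane as covariate, reversed in its test direction only) and proliferation (0.005 within lane 7). For KTS (6253 genes, 22 lists) leaving out 1 gave 3172 to 7531 genes (3172 without KTS046, 3610 without KTS093) and 17 to 23 lists, and an estimated correlation 0 lists. For the runs (599, 9 lists) DESeq2 gave 2159, the replicate block 2198, separate libraries 1127, leaving out 1 code 204 to 609 genes and 7 to 14 lists (14 without 15GFE019), an estimated correlation 0 lists and fry 2. For big against small (0 genes, 12 lists) DESeq2 gave 1 gene, an estimated correlation and fry 0 lists each, leaving out 1 library 0 genes and 7 to 13 lists (7 without the small library of 15GFE021), with cornified (-0.864 to 0.086), ciliated (-2.058 to 0.357), B and plasma cell (-0.382 to 1.067), adhesion (-0.269 to -0.002, reversed in its test direction only) and ribosomal (-0.247 to 0.025) lists reversed. The list spread (26) gave 23 to 27. The alveolar type 2 relation reversed with medians (0.245), and chemoattractants with neutrophils missed the threshold after adjustment within lane 7 (0.815), within 16GFE (0.807) and centred within the series (0.644). Same-code matches (2 of 6) were 5 by Pearson, 4 with 1000 genes and 6 when centred over the 4 shared codes. Log2 CPM of Pten moved with DESeq2 size factors (8.43 in KTS, 8.058 in KP) and with totals alone (8.317, 8.031), beyond its SD in KTS and beyond the 95% interval of its count in KP, a single library, and Cdkn2b at 0 counts in run 1 gave -2.626 with totals alone. All 16 named genes of 16GFE against 15GFE missed the threshold in at least 1 setting (180 of 352 values), as did 13 of 78 for KTS and 6 of 28 for the runs. A gene under about 1 CPM is limited by depth, and 1.83 M counts in 16GFE019 limit that library most.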

Other observations

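The tests of tumour cell share, of genotype, of lane for the library labelled KP and of depth for immediate early genes, and those with the background share, were chosen after the result was seen. The other tests were written down before they were run, but after the patterns themselves had been seen.

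The libraries labelled KTS lacked the Sox2 and squamous profile of the GFE libraries. Lane as the whole cause is argued against, since within lane 8 the median log2 fold change of the squamous list was -5.513 (SE over members 0.665). For fewer tumour cells among normal lung, the club list was lower (-2.788, SE over members 0.484) while the alveolar type 2 list was higher (2.53), as predicted if it were not the cause. If it were the cause, the ciliated, endothelial and T cell medians were also predicted above 0. The ciliated (-1.01) and T cell (-2.29) medians lay below 0, and the endothelial median (0.57) above. These values cannot decide, as no normal lung library shows whether such transcripts of GFE come from normal lung or tumour. Fewer tumour cells therefore stays open. Tumours of another genotype than the label stays open, a hypothesis, as the lower Cdkn2b level of the 2 was 13.8 CPM against at most 0.593 CPM in the 11 GFE libraries, and a mislabelled genotype may account for it. No biological explanation was tested beyond the label.

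The library labelled KP was low in Sox2 (5.03 CPM) and in the squamous list (score 2.66, GFE at least 6.27) but had Krt4 and Krt13 at log2 CPM of 8.22 and 8.10. Lane as the whole cause is argued against by its squamous score of 2.66, against 6.415 to 7.228 (SD 0.377) in the 4 16GFE libraries of its lane. Fewer tumour cells among normal lung stays open for it, since its club score of 5.73 lay within the range of the 11 GFE libraries (5.47 to 7.13). Tumours of another genotype than the label stays open, with Cdkn2b at 19.99 CPM. Biology was not tested.

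Silent genes, those with next to no counts in the 4 libraries of run 2 with the fewest olfactory receptor counts, took from 0.0773% to 0.824% of all counts in the 10 other libraries of run 2, all GFE. The lowest share was in 16GFE018 and the highest in 16GFE019. The X to autosome ratio of silent gene counts per kb ran from 0.766 to 1.63 and the Y to autosome ratio from 0 to 1.12. Both ratios went with Xist. Where Xist was at least 2551 CPM, the X ratio was at least 1.223 and the Y ratio at most 0.092. Where Xist was at most 12.93 CPM, the X ratio was at most 0.862 and the Y ratio at least 0.755. The source of these counts was left open.

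Immediate early genes were lower in 16GFE than in 15GFE (median -1.25, SE over members 0.157). This SE and those of the medians below are over genes and do not measure the spread between libraries. Background counts as the whole cause are argued against, since with their share as covariate the median was -0.82 (SE 0.135), although the folds shrank and Fos (-2.41 to -1.891, adjusted p = 0.0675), Egr1 (-2.68 to -1.868, 0.115), Junb (-1.27 to -1.045, 0.0584) and Dusp1 (-1.45 to -1.074, 0.132) lost their calls. With all libraries thinned to the smallest total the median was -1.127 (SE 0.149). Thinning keeps the expected CPM of each gene, so the median could hardly have moved. It therefore cannot decide on depth, which stays open. Lane is argued against by the median within lane 7, -1.226 (SE 0.160). The 16GFE libraries of lane 7 (16GFE001, 16GFE003 and 16GFE017) are among the 5 of highest olfactory receptor share. Their depth was 3.415 to 3.985 M counts, against at least 4.979 M in 15GFE. The comparison within lane 7 therefore removes lane but not background or depth. Run 1 holds no 16GFE library, so preparation of the 16GFE libraries stays open, as do tissue handling and tumour biology, which were not tested and may account for the difference.

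Of 100 drawn splits of the 11 libraries (330 possible), 2 gave at least 34 genes, the real one included, which argues against chance. The highest other split gave 1940 genes, which points to a structure of the samples. It set 15GFE019, 15GFE021, 16GFE018 and 16GFE011 against the other 7. These 4 have the lowest olfactory receptor shares of the 11 (at most 0.01275%, the others at least 0.01338%). With that share as covariate 3 genes were called for the code series. For lists, 6 of 100 splits gave as many as the real 21 (highest other 24), so chance cannot be excluded. For the runs the same codes pair the libraries, and only 8 splits part all pairs, too few for a share under 0.05. Among them 1 gave as many genes as the real 599 (highest other 0), and 5 gave as many lists as the real 9 (highest other 14). Over all 35 splits, whether or not they part the pairs, the others had a median of 11.5 lists.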
